A study of Mus musculus with 18 samples.

How the data were processed

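Per the labels' protocols and the design text, cortical interneurons of the caudal ganglionic eminence were sorted as GFP-positive cells from GAD65-GFP mice with or without a functional Htr3a gene. Each array held RNA pooled from at least 4 brains of 1 litter, and each group had 3 arrays from 3 different litters. Per the design text, the RNA was amplified and labelled by the Affymetrix small-scale protocol and hybridised to the Mouse Genome 430 2.0 array. Signals were read and normalised by the authors with robust multi-array averaging in Partek Genomic Suite 6.6, so the deposited values were log2 intensities, given to 2 decimals. No column of sample values was left unused.

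The values were used as deposited. The file held 45101 probe sets, of which 64 were controls. The array's annotation table named 1 gene for 34945 of them, several genes for 932 and none for 9160. Probe sets with a mean in the lowest 30% over the 18 arrays (under a log2 mean of 5.255) were left out. The probe set with the highest mean stood for each gene, which left 14292 genes tested, and 0 symbols were updated. Array values carry no counts, and the number of arrays limits the precision.

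Genes were compared with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 6 groups of age and genotype. All groups shared the estimate of the spread, with 12 residual degrees of freedom, and p-values were moderated and adjusted by Benjamini-Hochberg over all genes tested. A gene passed at an adjusted p under 0.05. The comparisons were Htr3a-KO against control at E14.5, E18.5 and P2, the mean of these 3 differences, the difference of the Htr3a-KO effect between ages (an F test and each pair of ages), and E18.5 against E14.5 and P2 against E18.5 in controls. Values in the text are group means ± SD over 3 arrays on the log2 scale unless SE is written. Differences are Htr3a-KO minus control, or later age minus earlier age.

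A total of 24 gene lists were fixed before the data were examined, as were the comparisons, the tests, most alternatives and the rule for named genes. The lists covered semaphorins, plexins and neuropilins, other guidance cues, migration machinery, GABAergic, CGE and MGE interneuron markers, striatal and excitatory neuron markers, cell cycle, neural progenitor, astrocyte, oligodendrocyte, microglia, endothelial, erythroid and meningeal markers. They also covered immediate early genes, serotonin receptors, GABA and glutamate receptors, voltage-gated channels, synaptic genes, cadherins, apoptosis and sex-linked genes. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. camera with an estimated correlation and fry were run beside it. Single members adjusted over the list alone are counted beside those that passed over all genes.

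The named genes of each genotype comparison were Htr3a, Plxna4, Sema3a, Nrp1, Gad1 and Gad2. To these came the 8 largest rises and 8 largest falls past the threshold with no overlap between groups (for the mean over ages, with 3 age differences of 1 sign), and up to 3 members of each list past the threshold with the smallest p. Where fewer than 5 genes passed, the 5 smallest p in each direction were given as values that did not pass. The age comparisons took the 6 largest rises, the 6 largest falls and up to 2 members of each list, and the interaction the 8 smallest p past the threshold. Gene models known only by a number were counted and not named. Some list members beyond this rule are given as examples of a list, chosen after their values were seen.

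The tests were tried on simulated values, the means of each gene plus noise drawn independently for each gene and array. Known changes were put into 200 of the 14292 genes. At 2-fold, the share recovered was 85.1% at E14.5, 80.6% at E18.5, 80.6% at P2 and 95.5% for the mean over ages. At 1.5-fold these shares were 47.8%, 41.8%, 43.3% and 82.1%. For the 2 age comparisons 88.1% and 79.1% of 2-fold changes were recovered, and for the interaction 58.2%. False calls numbered 10, 10, 6 and 10 in the genotype comparisons, 14 and 8 in the age comparisons and 3 in the interaction. A shift of 0.5 log2 in the microglia list was recovered by camera at an adjusted p of 1.81e-08 with 0 of the other lists called. Simulated genes did not move together as genes of real arrays can. These shares and false calls therefore do not give the error rates in the real arrays, least of all for lists.

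Calls near Htr3a were counted within 20 Mb on chromosome 9, with gene positions from the GRCm38.p6 assembly, by Fisher's exact test. Overlap of calls between ages was tested by Fisher's exact test. The alternatives were no filter and a stricter filter, the mean of a gene's probe sets, all probe sets, quantile normalization, median centring, trended and robust variance, array weights, a replicate block, a false discovery rate of 0.10, a change of at least 1.5-fold, only the 6 arrays compared, other windows, and leaving out each array in turn. Covariates for microglia and endothelial list means, leaving out the 2 arrays with the highest microglia list mean, and the whole of chromosome 9 were alternatives chosen after seeing the data.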

Results

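The series measured RNA levels in sorted cortical interneurons born in the caudal ganglionic eminence (CGE), a transient embryonic source of superficial cortical interneurons. The cells carried GFP under GAD65 control and came from Htr3a-KO and control mice. Htr3a encodes the serotonin-gated cation channel subunit that marks this interneuron class. The ages covered tangential migration at E14.5, entry into the cortical plate at E18.5 and settling in layers at P2, with 3 arrays for each of the 6 groups and 18 arrays in all. Array medians lay between 6.35 and 6.46 log2 units. Correlations between arrays were 0.984 to 0.996 within groups and 0.949 to 0.995 between groups. The first principal component held 54.8% of the variance, the second 14.1% and the third 7.18%. The number of arrays limits the precision of these values.

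RNA quality was read from the control probe sets. The Gapdh 3' to 5' difference was 1.55 to 2.2 over the arrays and that of actin 0.57 to 1.22. At E18.5, Gapdh gave 1.95 ± 0.17 in Htr3a-KO and 1.74 ± 0.10 in control (exact permutation test, two-sided, p = 0.2), and actin 1.01 ± 0.15 and 0.76 ± 0.24 (exact permutation test, two-sided, p = 0.3). The smallest p that 3 against 3 arrays allow is 0.1. Excitatory neuron RNA was present in every sorted sample, since Neurod6, a transcription factor of excitatory neurons, measured 8.91 to 12.38. Xist, the transcript of the inactive X, was 7.87 in E14.5 Htr3a-KO array 2 and 10.86 to 12.67 in the other arrays. Eif2s3y, a Y-linked gene, was 4.07 in E18.5 control array 2 and 8.25 to 9.78 elsewhere.

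The targeted gene, Htr3a, was measured by 1 probe set, and the labels do not state where it lies against the deleted part. Control arrays read 8.49, 7.99 and 7.65 at E14.5, 9.64, 10.79 and 10.58 at E18.5, and 8.61, 8.64 and 9.11 at P2. Htr3a-KO arrays read 7.41, 7.29 and 7.19 at E14.5, 6.61, 6.79 and 7.09 at E18.5, and 6.81, 7.01 and 6.71 at P2. Htr3a fell 11.4-fold at E18.5, from 10.34 ± 0.61 to 6.83 ± 0.24 (adjusted p = 7.66e-06), and 3.85-fold at P2, from 8.79 ± 0.28 to 6.84 ± 0.15 (adjusted p = 0.0109). At E14.5 the means were 8.04 ± 0.42 and 7.30 ± 0.11, a difference of −0.75 (SE 0.26) that did not pass (adjusted p = 0.708). Over the 3 ages Htr3a fell 4.19-fold (adjusted p = 3.99e-06). Every Htr3a-KO array lay below every control array of its age. The P2 call was lost without P2 Htr3a-KO array 3, where the difference was −1.88 (adjusted p = 0.121), with 0.00658 to 0.121 over all its alternatives.

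**Figure D1:**
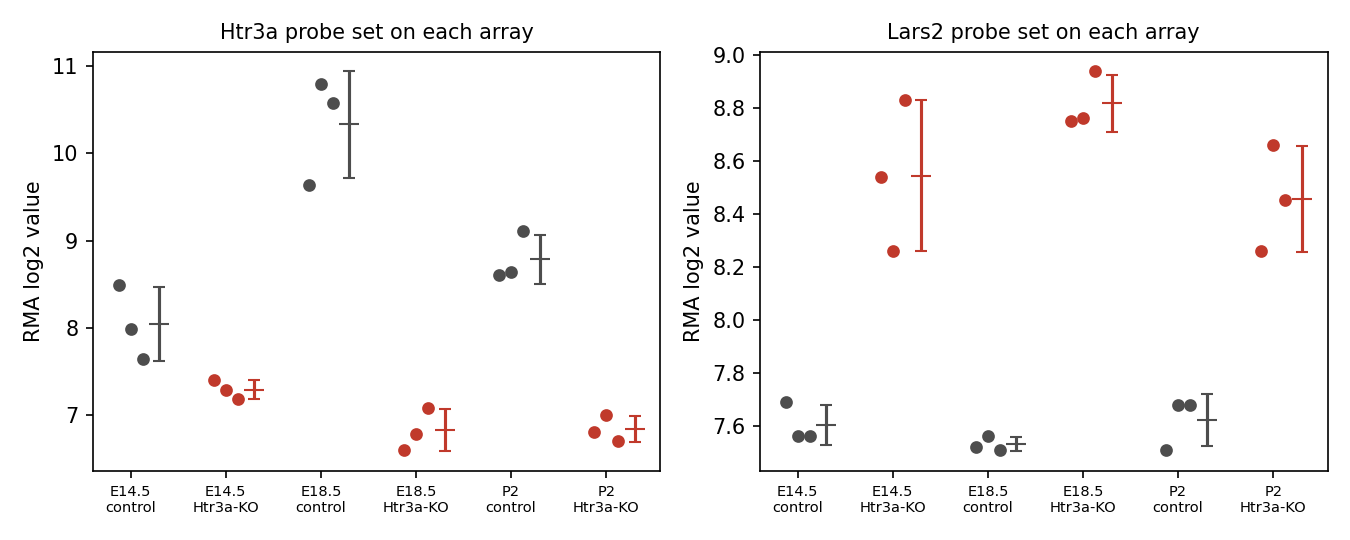
Log2 RMA value of Htr3a and of Lars2 in each of the 18 arrays, by age and genotype; points are arrays and bars the mean ± SD of 3 arrays. Htr3a was lower in Htr3a-KO at each age, at 6.83 against 10.34 at E18.5, and Lars2 was higher, at 8.82 against 7.53. The Lars2 values are from its probe set with the highest mean, and another of its probe sets gave −0.28 over the 3 ages.

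Between E14.5 and E18.5 some receptor, channel and immediate early genes rose in control samples. Gria2, a subunit of AMPA-type glutamate receptors, rose 2.21-fold from 10.31 to 11.46 (adjusted p = 1.28e-04, n = 3 arrays per age, limma), and Grin3a, an NMDA receptor subunit, rose 2.93-fold. The potassium channel gene Kcnc2 rose 5.24-fold (adjusted p = 5.60e-04). Among immediate early genes, which neuronal activity and tissue handling induce, Egr1 rose 4.15-fold from 10.41 ± 0.49 to 12.47 ± 0.07 and Fos 3.93-fold. Htr3a itself rose 4.90-fold, and Ndnf, a marker of neurogliaform cells, 3.86-fold. In limma 1571 genes passed, 866 higher and 705 lower, against 3645 genes at an unadjusted p under 0.05. Groups of 3 and 3 arrays did not overlap for 4413 genes (30.9%), where chance gives 10%.

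The fixed lists put these genes in groups. Of 27 GABA and glutamate receptor genes 10 rose and 1 fell (16 adjusted over the list alone), and camera placed the list higher (adjusted p = 1.70e-08, and adjusted p = 0.122 with an estimated correlation). Of 31 voltage-gated channel genes 9 rose and 0 fell (9 adjusted over the list alone; adjusted p = 7.64e-06, and adjusted p = 0.208 with an estimated correlation). For synaptic genes it was 9 of 30 up and 0 down (16 adjusted over the list alone), with Nlgn3 at +0.97 and Rims1 at +1.29 (adjusted p = 1.73e-07, and adjusted p = 0.208 with an estimated correlation). Immediate early genes had 12 of 25 up and 0 down (13 adjusted over the list alone; adjusted p = 2.77e-09, and adjusted p = 0.122 with an estimated correlation).

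Guidance genes moved singly. Nrp2, a co-receptor for class 3 semaphorins, fell 5.38-fold from 9.61 ± 0.17 to 7.18 ± 0.20 (adjusted p = 8.24e-05), and Sema6d fell 2.76-fold from 11.58 ± 0.27 to 10.11 ± 0.28 (adjusted p = 1.95e-04). Of 29 semaphorin, plexin and neuropilin genes 2 rose and 5 fell (10 adjusted over the list alone; camera adjusted p = 0.952). Among 42 other guidance genes 1 rose and 6 fell (10 adjusted over the list alone), Nrg1 by −0.86 and the netrin receptor Dcc by −1.17 (camera adjusted p = 0.185). The migration machinery had 5 of 40 up and 2 down (8 adjusted over the list alone; camera adjusted p = 0.120), with Mapt at +0.99. Cadherins had 1 of 27 up and 1 down (2 adjusted over the list alone), with Pcdh11x at +1.26.

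Striatal projection neuron genes fell and oligodendrocyte lineage genes rose in control samples over the same step. Of the striatal list, Isl1 changed by −5.76 from 11.06 ± 1.83 to 5.30 ± 0.17 (−5.16 without E14.5 control array 2 and −6.81 without array 3) and Ebf1 by −4.90 from 9.40 ± 1.62 to 4.50 ± 0.28, with 7 of 13 down and 0 up (9 adjusted over the list alone; adjusted p = 2.44e-07, and adjusted p = 0.122 with an estimated correlation). Zfp503 fell by 4.03, Zfhx3 13.6-fold, Crabp1 by 3.03 and the embryonic globin gene Hbb-y by 3.96. The E18.5 means of Ebf1, Crabp1 and Hbb-y and the E14.5 mean of Mlip lay below 5.255, the level of the filter on dim probe sets. The E18.5 mean of Isl1 and the E14.5 means of Olig2 and Slco1c1 (5.58) lay near it. The log2 differences of these genes are differences of array readings against a dim level, and they do not set the size of the RNA change. Among oligodendrocyte lineage genes Olig1 rose 31.8-fold from 7.25 ± 0.04 to 12.24 ± 0.65, Pdgfra 15.3-fold and Olig2 by 3.41. In that list 8 of 12 rose and 0 fell (9 adjusted over the list alone; adjusted p = 5.37e-07, and adjusted p = 0.122 with an estimated correlation). Egfr rose 15.0-fold from 5.81 to 9.71, Tnc by 2.93, Nwd2 by 3.69, Mlip by 3.52, Slco1c1 by 2.90 and Aldh1l1 by 1.67.

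CGE markers had 6 of 20 up and 2 down (11 adjusted over the list alone; adjusted p = 0.0454, and adjusted p = 0.552 with an estimated correlation). Of 9 GABAergic genes 0 rose and 2 fell (3 adjusted over the list alone; adjusted p = 0.00754, and adjusted p = 0.552 with an estimated correlation), the homeobox genes Dlx6 (−2.17) and Dlx5 (−1.21). Excitatory neuron markers had 2 of 17 up and 6 down (9 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.501 with an estimated correlation), with Neurog2 at −1.57 and Sstr2 at −0.83. Endothelial markers had 1 of 17 up (adjusted p = 0.0329, and adjusted p = 0.734 with an estimated correlation) and cell cycle genes 0 of 30 (adjusted p = 0.0329, and adjusted p = 0.777 with an estimated correlation). The CGE call was lost without E14.5 control array 3 (0.137) or E18.5 control array 2 (0.151), and the excitatory call without E14.5 control array 3 (0.0927). The GABAergic call was lost without E14.5 control array 1 (0.126) or 2 (0.0589), the endothelial call without E14.5 control array 1 (0.0596) or 2 (0.125) or E18.5 control array 3 (0.405), and the cell cycle call without E14.5 control array 3 (0.230) or E18.5 control array 1 (0.604). Dlx6 no longer passed without E14.5 control array 1 (adjusted p = 0.0595) or 2 (0.0559), nor Dlx5 without E14.5 control array 1 (0.183) or 2 (0.159) or E18.5 control array 1 (0.120), 2 (0.0868) or 3 (0.0822), nor with quantile normalization (0.0566, with 8.00e-04 to 0.183 over its alternatives). The count of 1571 fell to 916 without E14.5 control array 1, to 1039 without E14.5 control array 2, to 938 without E18.5 control array 1 and to 926 without E18.5 control array 3.

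Among the remaining lists, MGE interneuron markers between E14.5 and E18.5 had 2 of 15 up and 2 down (4 adjusted over the list alone), with the kainate receptor gene Grik3 at −1.17. Progenitor markers had 4 of 20 up and 2 down (8 adjusted over the list alone; camera adjusted p = 0.0866). Astrocyte markers had 1 of 12 up, microglia markers 0 of 18, erythroid markers 1 of 8 down, meningeal markers 0 of 10 and sex-linked genes 0 of 4. Serotonin receptors had 1 of 8 up, which was Htr3a. Apoptosis genes had 1 of 20 up and 2 down.

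From E18.5 to P2 glial RNA rose in control samples. Aqp4, the water channel of astrocyte endfeet, rose by 6.08 from 4.56 ± 1.20 to 10.64 ± 0.74 (adjusted p = 1.25e-06, n = 3 arrays per age, limma), and Apoe by 4.32 from 7.85 to 12.17 (adjusted p = 1.95e-05). The gap junction gene Gja1 rose 16.7-fold and the glutamate transporter gene Slc1a2 9.76-fold. Gpr17, a receptor of immature oligodendrocytes, rose 7.75-fold and Lhfpl3 4.68-fold. Pla2g7 rose 17.1-fold, Car8 13.1-fold and Gabrg1 8.48-fold. Crh, a neuropeptide of some CGE interneurons, rose by 3.69 from 4.60 to 8.28 (adjusted p = 5.78e-06). The E18.5 means of Aqp4 and Crh lay below the filter level of 5.255. Their log2 differences are differences of array readings against a dim level, and they do not set the size of the RNA change. In limma 2818 genes passed, 1424 higher and 1394 lower, against 4719 at an unadjusted p under 0.05. Without E18.5 control array 1 the count was 1823, and without P2 control array 2 it was 1856. Groups did not overlap for 4692 genes (32.8%; chance 10%).

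The lists showed the same split. Astrocyte markers had 10 of 12 up and 0 down (10 adjusted over the list alone; adjusted p = 1.47e-12, and adjusted p = 0.0700 with an estimated correlation). Oligodendrocyte markers also had 10 of 12 up and 0 down (10 adjusted over the list alone; adjusted p = 1.10e-08, and adjusted p = 0.111 with an estimated correlation). Progenitor markers had 11 of 20 up (14 adjusted over the list alone), with Slc1a3 up 7.09-fold and Aldoc, which the astrocyte list shares, up 7.14-fold (adjusted p = 2.82e-07, and adjusted p = 0.472 with an estimated correlation). Microglia markers had 4 of 18 up (13 adjusted over the list alone, camera adjusted p = 3.88e-06, and adjusted p = 0.472 with an estimated correlation), with Mrc1 up 6.08-fold and Pf4 by 1.80. Over all their alternatives the limma adjusted p was 0.00161 to 0.0884 for Mrc1 and 6.54e-04 to 0.133 for Pf4, so both calls were lost in some. The microglia list mean rose by 1.67, and by 0.95 without P2 control array 1. Endothelial and mural markers had 3 of 17 up (4 adjusted over the list alone; adjusted p = 4.42e-05, and adjusted p = 0.472 with an estimated correlation), with Slco1c1 at +2.54. Meningeal markers had 3 of 10 up (4 adjusted over the list alone; adjusted p = 0.00419, and adjusted p = 0.472 with an estimated correlation), Col1a2 at +1.23 and Igfbp2 at +0.95. The meningeal call was lost without E18.5 control array 2 (0.0555) or P2 control array 3 (0.0505).

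Excitatory lineage genes fell from E18.5 to P2. The proneural gene Neurog2 fell 7.59-fold from 8.95 to 6.03 (adjusted p = 1.98e-05), and Eomes, a marker of intermediate progenitors, fell 7.31-fold from 9.73 to 6.86 (adjusted p = 2.55e-04). Neurod1 fell 3.75-fold, Shisa2 4.54-fold, Rspo3 4.08-fold and Insm1 3.47-fold. Of 17 excitatory markers 0 rose and 9 fell (9 adjusted over the list alone; adjusted p = 0.00402, and adjusted p = 0.472 with an estimated correlation). Htr3a fell 2.93-fold from 10.34 to 8.79 (adjusted p = 8.34e-04), and Sst, a neuropeptide of MGE interneurons, fell 2.29-fold (adjusted p = 0.00419).

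Guidance receptors also moved after birth. The ephrin receptor gene Epha3 fell 3.41-fold from 11.21 to 9.44 (adjusted p = 7.70e-05) and the ephrin gene Efnb2 1.90-fold. Sema6a rose 2.18-fold from 7.46 to 8.58 (adjusted p = 7.64e-04) and Sema5b 2.49-fold. Of 29 semaphorin, plexin and neuropilin genes 6 rose and 4 fell (10 adjusted over the list alone; camera adjusted p = 0.422). Among 42 other guidance genes 3 rose and 6 fell (12 adjusted over the list alone; camera adjusted p = 0.390). Migration machinery had 2 of 40 up and 2 down (2 adjusted over the list alone), with Cdkn1c down 2.16-fold. Cadherins had 5 of 27 up and 2 down (7 adjusted over the list alone), Pcdh11x 3.58-fold and Pcdh10 by 1.48.

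Neuronal lists were also tested at this step. GABA and glutamate receptors had 7 of 27 up and 1 down (8 adjusted over the list alone), with Grin3a at +1.42 (adjusted p = 0.00455, and adjusted p = 0.472 with an estimated correlation). Voltage-gated channels had 4 of 31 up and 0 down, Kcna2 at +1.11 and Kcnd2 at +0.98. Immediate early genes had 8 of 25 up and 1 down (9 adjusted over the list alone; adjusted p = 0.00387, and adjusted p = 0.472 with an estimated correlation), Zfp36 6.19-fold and Ccn1 4.89-fold. That call was lost without E18.5 control array 2 (0.131). CGE markers had 3 of 20 up and 1 down, MGE markers 0 of 15 up and 2 down, and serotonin genes 3 of 8 up and 1 down, with the monoamine oxidase gene Maob at +1.21. Synaptic genes had 2 of 30 up, GABAergic genes 1 of 9 up, apoptosis genes 2 of 20 up and 1 down, and cell cycle genes 1 of 30 down. Striatal, erythroid and sex-linked genes had 0 past the threshold of 13, 8 and 4 measured.

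At E14.5, while the cells migrate tangentially, loss of Htr3a went with changes in 2 genes. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, rose 1.92-fold from 7.60 ± 0.08 to 8.54 ± 0.29 (adjusted p = 0.0186, n = 3 arrays per genotype, limma). Pop1, a protein subunit of RNase P, fell 1.74-fold from 8.07 ± 0.12 to 7.28 ± 0.17 (adjusted p = 0.0158). Values that did not pass were Slco1c1 at +1.60 (adjusted p = 0.173), Abhd14a at +1.18 (0.186), Col19a1 at +1.10 (0.103) and Mmp2 at +0.79 (0.278). On the lower side these were Tmem25 at −0.85 (0.109), Dis3l at −0.67 (0.173), Pts at −0.55 (0.166) and Fam216a at −0.52 (0.226). At an unadjusted p under 0.05 there were 838 genes, where chance gives 715, and groups did not overlap for 1288 genes (9.01%, chance 10%). The GABA synthesis genes gave 11.84 ± 0.83 and 11.59 ± 0.34 for Gad1 (adjusted p = 0.996) and 10.76 ± 1.24 and 10.21 ± 0.29 for Gad2 (0.969) in control and Htr3a-KO. Pop1 no longer passed without control array 1 (adjusted p = 0.0738) or Htr3a-KO array 1 (0.137), and Lars2 without control array 1 (0.0738), control array 2 (0.118) or Htr3a-KO array 1 (0.137). The count was 0 without control array 1, 1 without control array 2, 135 without control array 3, 0 without Htr3a-KO array 1 and 11 without Htr3a-KO array 3. With the mean of a gene's probe sets Lars2 gave 0.23 (0.719) and Pop1 −0.42 (0.497), and neither passed with only the 6 arrays compared (0.921), with a range over alternatives of 0.00486 to 0.921 for Pop1 and 0.00268 to 0.921 for Lars2.

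Microglia, vessel, meningeal and erythroid markers were higher in E14.5 Htr3a-KO samples. Microglia list means were 7.94 ± 1.0 in Htr3a-KO and 6.62 ± 0.70 in control, with 18 of 18 members higher and 0 past the threshold (0 adjusted over the list alone; adjusted p = 1.19e-10, and adjusted p = 0.281 with an estimated correlation). Csf1r, the colony stimulating factor receptor of microglia, was 10.77 ± 1.23 against 8.43 ± 1.34. The list mean was highest in Htr3a-KO array 1, at 9.01, and without that array the difference of 1.31 was 0.77. Endothelial and mural markers averaged 7.54 ± 0.59 against 6.54 ± 0.37, with 0 of 17 past the threshold and 6 adjusted over the list alone (adjusted p = 3.03e-12, and adjusted p = 0.269 with an estimated correlation). Meningeal genes differed by 0.61 on average, with 0 of 10 past the threshold and 3 adjusted over the list alone (adjusted p = 4.99e-05, and adjusted p = 0.269 with an estimated correlation). Erythroid genes differed by 0.47, with 0 of 8 past the threshold (adjusted p = 0.00785, and adjusted p = 0.152 with an estimated correlation), and that call was lost without Htr3a-KO array 1 (0.0606). The erythroid difference was 0.21 without Htr3a-KO array 1 and 0.71 without Htr3a-KO array 2. Astrocyte markers were not called (camera adjusted p = 0.0776, and 0.0381 with median centring), nor were oligodendrocyte markers (0.593).

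Striatal projection neuron markers were lower in E14.5 Htr3a-KO samples, at 8.45 ± 0.51 against 9.45 ± 0.98, with 13 of 13 members lower, 0 past the threshold and 1 adjusted over the list alone (adjusted p = 1.51e-08, and adjusted p = 0.152 with an estimated correlation). The difference was −0.59 without control array 2 and −1.54 without control array 3. Isl1 was 8.64 ± 2.17 against 11.06 ± 1.83. Control array 3 stood apart, with a striatal mean of 8.36 against 9.71 and 10.26, Gad2 at 9.34 against 11.57 and 11.38, and Gad1 at 10.88 against 12.34 and 12.29. GABAergic markers averaged −0.37, with 0 of 9 past the threshold (adjusted p = 0.0129, and adjusted p = 0.614 with an estimated correlation). That call was lost without control array 1 (0.682), control array 2 (0.342) or Htr3a-KO array 3 (0.0926), and the average was −0.07, −0.13 and −0.91 without control array 1, 2 and 3. MGE markers averaged 0.21, with 0 of 15 past the threshold (adjusted p = 0.0135, and adjusted p = 0.281 with an estimated correlation), lost without control array 3 (0.217) or Htr3a-KO array 1 (0.0635). Immediate early genes were 8.83 ± 0.20 against 8.46 ± 0.21, with 0 of 25 past the threshold and 1 adjusted over the list alone (adjusted p = 1.34e-05, and adjusted p = 0.271 with an estimated correlation). Voltage-gated channels averaged 0.22, with 0 of 31 past the threshold (adjusted p = 5.42e-04, and adjusted p = 0.370 with an estimated correlation). CGE markers had 0 of 20 past the threshold and 2 adjusted over the list alone (camera adjusted p = 0.215). Semaphorins, plexins and neuropilins had 0 of 29 past the threshold (camera adjusted p = 0.221), other guidance genes 0 of 42 (0.784) and migration machinery 0 of 40 (0.683).

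**Figure D2:**
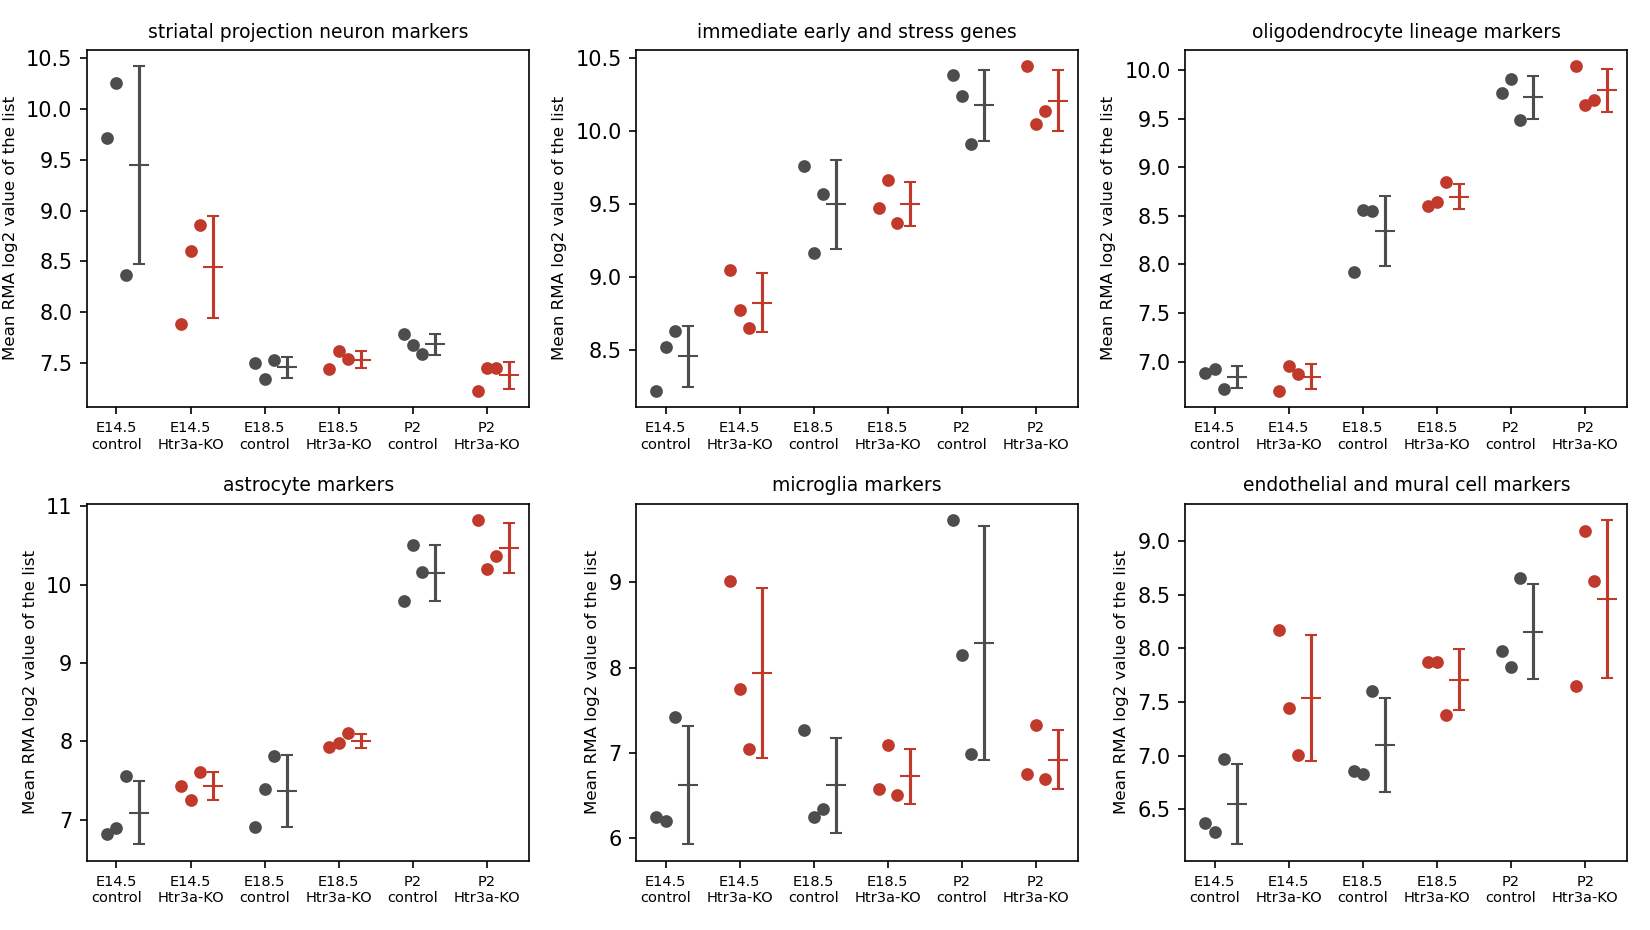
Mean log2 value of 6 marker lists in each of the 18 arrays, by age and genotype; points are arrays and bars the mean ± SD of 3 arrays. Microglia means were highest in E14.5 Htr3a-KO array 1 (9.01) and P2 control array 1 (9.73), and striatal means in E14.5 control arrays 2 (10.26) and 1 (9.71).

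At E18.5, as cells enter the cortical plate, 3 genes changed with loss of Htr3a. Beside Htr3a, Lars2 rose 2.44-fold from 7.53 ± 0.03 to 8.82 ± 0.11 (adjusted p = 3.31e-04, n = 3 arrays per genotype, limma). Pts, an enzyme of tetrahydrobiopterin synthesis, the cofactor for making serotonin and dopamine, fell 1.58-fold from 8.90 ± 0.07 to 8.24 ± 0.07 (adjusted p = 0.0390). Pts lies within 10 Mb of Htr3a on chromosome 9. Whether its fall came from the loss of Htr3a or from a DNA difference nearby was not tested. The classical MHC class I gene H2-K1 was 7.96 ± 0.28 in control and 9.76 ± 0.16 in Htr3a-KO and did not pass (adjusted p = 0.0738). Nor did Adhfe1 at +1.18 (0.0670), Rlf at +1.01 (0.0670), Snhg3 at +1.01 (0.0823), Vps52 at −1.69 (0.0738), Dis3l at −0.68 (0.0823) or the immediate early gene Nr4a3 at −1.45 (0.0823). Gad1 was 11.72 ± 0.14 in control and 11.15 ± 0.20 in Htr3a-KO (adjusted p = 0.444), and Gad2 9.67 ± 0.59 and 9.36 ± 0.04 (adjusted p = 0.795). At an unadjusted p under 0.05 there were 1844 genes, and groups did not overlap for 2965 genes (20.7%, chance 10%). Probe sets without a single gene name, given below, may carry a factor of single arrays at this age. Whether it adds to these counts or to the lists at E18.5 was not tested. The Pts call was lost without control array 1 (0.151), 2 (0.117) or 3 (0.0551) and without Htr3a-KO array 1 (0.163), 2 (0.109) or 3 (0.181). The count was 20 without control array 3. Lars2 no longer passed with the mean of its probe sets, at 0.29 (adjusted p = 0.168, and 3.09e-06 to 0.168 over its alternatives).

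Progenitor and glial lists were higher in E18.5 Htr3a-KO samples, with 0 members past the threshold in each. Progenitor markers averaged 0.54, with 0 of 20 past the threshold and 2 adjusted over the list alone (adjusted p = 2.50e-08, and adjusted p = 0.293 with an estimated correlation). Hes5, a Notch target, was 10.31 ± 0.24 against 8.71 ± 0.94. Astrocyte markers averaged 0.63, with 1 of 12 adjusted over the list alone (adjusted p = 1.58e-05, and adjusted p = 0.293 with an estimated correlation), and Aqp4 was 6.24 ± 0.16 against 4.56 ± 1.20. Endothelial markers averaged 0.61 over 17 genes (adjusted p = 1.12e-05, and adjusted p = 0.355 with an estimated correlation). Cell cycle genes averaged 0.30 over 30 genes (adjusted p = 7.98e-06, and adjusted p = 0.554 with an estimated correlation), and Mki67, a marker of dividing cells, was 10.96 ± 0.53 against 10.41 ± 0.43. Oligodendrocyte markers averaged 0.35 over 12 genes (adjusted p = 0.00204, and adjusted p = 0.355 with an estimated correlation), a call lost without control array 1 (0.0880). Without control array 1 the averages were 0.30 for progenitor, 0.40 for astrocyte, 0.09 for cell cycle and 0.14 for oligodendrocyte genes. The cell cycle average was 0.50 without control array 2 and 0.07 without Htr3a-KO array 3. Without control array 2 the number of lists called fell from 11 to 7.

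Guidance and adhesion lists were placed higher by camera at E18.5, with averages that depended on the scaling. With median centring these averages were 0.0067 for semaphorins, plexins and neuropilins, 0.03 for other guidance genes, 0.14 for cadherins, 0.09 for receptors and 0.07 for channels. That scaling moved the median of all genes from −0.06 to −0.15. The semaphorin, plexin and neuropilin list averaged 0.09, with 0 of 29 past the threshold and 1 adjusted over the list alone (adjusted p = 0.0240, and adjusted p = 0.293 with an estimated correlation), a call lost without control array 2 (0.0567) or Htr3a-KO array 1 (0.117). Other guidance genes averaged 0.12 over 42 genes (adjusted p = 0.00204, and adjusted p = 0.293 with an estimated correlation). Cadherins averaged 0.23 over 27 genes (adjusted p = 9.90e-05, and adjusted p = 0.293 with an estimated correlation). GABA and glutamate receptors averaged 0.18 (adjusted p = 0.00225, and adjusted p = 0.355 with an estimated correlation), lost without control array 2 (0.0567), Htr3a-KO array 1 (0.0861) or 2 (0.0627), with averages of 0.11, 0.12 and 0.31 without Htr3a-KO array 1, 2 and 3. Voltage-gated channels averaged 0.16 (adjusted p = 0.00166, and adjusted p = 0.355 with an estimated correlation), lost without control array 2 (0.130), where the average was 0.07, and 0.25 without Htr3a-KO array 3. Without control array 2 cadherins averaged 0.10. The sex-linked genes averaged 1.09 over 4 genes (adjusted p = 0.0240, and adjusted p = 0.293 with an estimated correlation), and this was lost without control array 2 (0.921, average 0.11), the array with Eif2s3y at 4.07, and the average was 1.68 without control array 1. Microglia means were 6.72 ± 0.32 and 6.62 ± 0.56 in Htr3a-KO and control.

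At P2, when cells settle in layers, 5 genes differed. Pts fell 1.82-fold from 8.99 ± 0.17 to 8.13 ± 0.05 (adjusted p = 0.00425, n = 3 arrays per genotype, limma), and Htr3a fell 3.85-fold. Dis3l, an exosome ribonuclease, fell 1.77-fold from 7.86 ± 0.21 to 7.04 ± 0.09 (adjusted p = 0.0307). Lars2 rose 1.78-fold from 7.62 ± 0.10 to 8.46 ± 0.20 (adjusted p = 0.0307). The MHC class II gene H2-Aa rose by 0.64 from 5.55 ± 0.14, near the filter level, to 6.19 ± 0.14 (adjusted p = 0.0307). Gad1 was 11.58 ± 0.18 in control and 11.55 ± 0.32 in Htr3a-KO (adjusted p = 0.991), and Gad2 9.24 ± 0.18 and 8.92 ± 0.42 (0.901). At an unadjusted p under 0.05 there were 1083 genes, and groups did not overlap for 1306 genes (9.14%, chance 10%). Pts no longer passed without Htr3a-KO array 3 (0.0538), and Dis3l without control array 1 (0.174) or 2 (0.229) or Htr3a-KO array 1 (0.129), 2 (0.0949) or 3 (0.124). Lars2 no longer passed without control array 1 (0.181) or 2 (0.159) or Htr3a-KO array 2 (0.0949) or 3 (0.137), nor H2-Aa without control array 1 (0.174) or Htr3a-KO array 2 (0.0577) or 3 (0.137). The count was 3 without control array 2, 21 without control array 3, 2 without Htr3a-KO array 2 and 0 without Htr3a-KO array 3. With only the 6 arrays compared 0 genes passed. With the mean of its probe sets Lars2 gave 0.23 (adjusted p = 0.625). Over all alternatives the adjusted p was 0.0105 to 0.811 for Lars2, 0.0105 to 0.811 for Dis3l, 0.0122 to 0.901 for H2-Aa and 0.00125 to 0.618 for Pts.

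Microglia genes were lower in P2 Htr3a-KO samples, at 6.92 ± 0.35 against 8.29 ± 1.38, with 0 of 18 past the threshold and 2 adjusted over the list alone (adjusted p = 4.18e-09, and adjusted p = 0.657 with an estimated correlation). Control array 1 read 9.73 and control array 2 8.15, and without control array 1 the difference of −1.37 was −0.65. Pf4, a chemokine of border macrophages, was 6.84 ± 0.61 against 8.76 ± 0.99. Excitatory neuron markers were 8.02 ± 0.41 against 8.47 ± 0.04, with 0 of 17 past the threshold (adjusted p = 0.00101, and adjusted p = 0.657 with an estimated correlation), a call lost without control array 3 (0.0568) or Htr3a-KO array 1 (0.147, difference −0.22). Astrocyte markers averaged 0.32 over 12 genes (adjusted p = 0.00332, and adjusted p = 0.657 with an estimated correlation), lost without control array 1 (0.199) or Htr3a-KO array 1 (0.147), with an average of 0.14 in both cases and 0.49 without control array 2. Progenitor markers averaged 0.21 over 20 genes (adjusted p = 0.00431, and adjusted p = 0.794 with an estimated correlation), lost without control array 1 (0.316), Htr3a-KO array 1 (0.0790) or 3 (0.0761). The progenitor average was 0.07 and 0.31 without control array 1 and 2, and 0.11 and 0.34 without Htr3a-KO array 1 and 2. Endothelial markers averaged 0.30 over 17 genes (adjusted p = 0.00330, and adjusted p = 0.794 with an estimated correlation), lost without control array 1 (0.0604) or 2 (0.176) or Htr3a-KO array 2 (0.539) or 3 (0.0761). The endothelial average was 0.14 and 0.56 without control array 2 and 3, and 0.71 and −0.01 without Htr3a-KO array 1 and 2. Immediate early genes averaged 0.03 over 25 genes, and −0.10 to 0.135 without each of the 6 arrays in turn (adjusted p = 0.0445, and adjusted p = 0.794 with an estimated correlation), lost without control array 2 (0.102) or 3 (0.225), without Htr3a-KO array 1 (0.346) or 3 (0.0775), and with median centring (0.0820). Semaphorins, plexins and neuropilins had 0 of 29 past the threshold (camera adjusted p = 0.765), other guidance genes 0 of 42 (0.568) and migration machinery 0 of 40 (0.535). The number of lists called was 3 without control array 1 and 3 without Htr3a-KO array 3.

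Averaged over the 3 ages, with 9 arrays per genotype, 42 genes changed with loss of Htr3a, 23 higher and 19 lower. Lars2 rose 2.03-fold (1.02, SE 0.08, adjusted p = 3.99e-06) in 1 of its 3 probe sets, while another gave −0.28. Pts fell 1.61-fold (−0.69, SE 0.06, adjusted p = 1.69e-05). H2-K1, which presents peptides on the cell surface, rose 2.67-fold (1.42, SE 0.18, adjusted p = 0.00246), by 1.52 at E14.5, 1.80 at E18.5 and 0.92 at P2. H2-D1, another MHC class I gene, rose 2.27-fold (adjusted p = 0.0282), by 1.32, 1.51 and 0.72. Slco1c1, the thyroxine transporter of brain vessels, rose 2.15-fold (adjusted p = 0.0130), and the cytokine gene Il18 1.82-fold (adjusted p = 0.0148). The E14.5 control mean of Slco1c1, 5.58, lay near the filter level. The calcium channel subunit gene Cacna2d2 rose 1.88-fold, Abhd14a 1.79-fold and the phosphatase gene Ppm1m 1.65-fold. Mid1, a microtubule-associated ubiquitin ligase, fell 2.24-fold (adjusted p = 0.0130), the ribosomal protein gene Rps25 1.77-fold (adjusted p = 0.0103), Dis3l 1.65-fold, Abhd1 1.62-fold, Tmem25 1.61-fold and Cep164, a gene of the mother centriole, 1.57-fold. At an unadjusted p under 0.05 there were 1600 genes. With quantile normalization 37 genes passed, 24 higher and 13 lower.

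Some of these calls rested on single arrays. Without E14.5 control array 1 the count was 19, without E14.5 control array 2 also 19, without E14.5 control array 3 it was 128 and without E14.5 Htr3a-KO array 1 it was 20. Leaving out E18.5 control array 1 or 2 gave 21 and 26 genes, and E18.5 Htr3a-KO array 2 or 3 gave 22 and 19. Leaving out P2 control array 1 gave 20 genes, and P2 Htr3a-KO array 2 or 3 gave 26 and 17. Ppm1m was lost without E14.5 control array 1 (0.0629) or 2 (0.0723), E18.5 Htr3a-KO array 2 (0.0510) or 3 (0.0620), P2 control array 1 (0.0597) or P2 Htr3a-KO array 1 (0.0530) or 3 (0.0529). H2-D1 was lost without E14.5 control array 2 (0.0723) or Htr3a-KO array 1 (0.0549), E18.5 Htr3a-KO array 1 (0.0613), 2 (0.0613) or 3 (0.0537), or P2 control array 2 (0.0524) or Htr3a-KO array 2 (0.0589) or 3 (0.0716). Cacna2d2 passed only when the array left out was E14.5 control 3, E18.5 Htr3a-KO 1 or 3 or P2 control 3, and each of the other 14 gave an adjusted p of 0.0508 to 0.0858. Abhd1 passed only when it was E14.5 control 3, P2 control 2 or 3 or P2 Htr3a-KO 1, and each of the other 14 gave 0.0600 to 0.118. The remaining 12 named genes that passed over the 3 ages passed without any 1 of the 18 arrays. With the mean of a gene's probe sets Tmem25 gave −0.34 (0.0745, with 2.09e-04 to 0.0745 over its alternatives) and Cep164 −0.15 (0.355). With microglia and endothelial list means as covariates, chosen after seeing the data, 10 genes passed, and Abhd1 (0.419), Cacna2d2 (0.325), Slco1c1 (0.261), itself a member of the endothelial list, Rps25 (0.177), Cep164 (0.105), H2-D1 (0.10), Abhd14a (0.0797), Mid1 (0.0778) and Il18 (0.0778) did not. Their differences were then −0.53 for Abhd1, 0.80 for Cacna2d2, 0.86 for Slco1c1, −0.58 for Rps25, −0.63 for Cep164, 1.08 for H2-D1, 0.87 for Abhd14a, −1.20 for Mid1 and 0.98 for Il18, against −0.70, 0.91, 1.10, −0.82, −0.65, 1.19, 0.84, −1.16 and 0.87 before. Over all their alternatives the adjusted p ranged from 0.00343 to 0.419 for Abhd1, from 0.00150 to 0.325 for Cacna2d2, from 4.43e-04 to 0.261 for Slco1c1, from 8.70e-04 to 0.177 for Rps25, from 0.00143 to 0.355 for Cep164, from 0.00268 to 0.10 for H2-D1, from 0.00247 to 0.0797 for Abhd14a, from 0.00135 to 0.0778 for Mid1 and from 0.00154 to 0.133 for Il18.

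Vascular, glial and progenitor lists were higher in Htr3a-KO over the 3 ages. Endothelial and mural markers averaged 0.64, with 1 of 17 past the threshold, Slco1c1, and 11 adjusted over the list alone (adjusted p = 4.99e-14, and adjusted p = 0.368 with an estimated correlation). Astrocyte markers averaged 0.43, with 0 of 12 past the threshold and 3 adjusted over the list alone (adjusted p = 3.09e-07, and adjusted p = 0.368 with an estimated correlation). Progenitor markers averaged 0.32, with 0 of 20 past the threshold and 1 adjusted over the list alone (adjusted p = 2.57e-08, and adjusted p = 0.388 with an estimated correlation). Immediate early genes averaged 0.13 (0.08 without E18.5 control array 2 and 0.09 without P2 control array 3), with 0 of 25 past the threshold and 3 adjusted over the list alone (adjusted p = 1.43e-04, and adjusted p = 0.388 with an estimated correlation). Meningeal genes had 0 of 10 past the threshold (adjusted p = 0.00363, and adjusted p = 0.388 with an estimated correlation), and voltage-gated channels 1 of 31, Cacna2d2 (adjusted p = 2.34e-04, and adjusted p = 0.388 with an estimated correlation). Striatal markers averaged −0.41, with 0 of 13 past the threshold (adjusted p = 0.00815, and adjusted p = 0.408 with an estimated correlation). That average came mostly from E14.5 (−1.0), with 0.08 at E18.5, placed higher by camera (adjusted p = 0.148, and 0.0242 with median centring, at a mean of −0.01), and −0.31 at P2.

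Cell cycle genes (0.00128, and adjusted p = 0.595 with an estimated correlation), oligodendrocyte markers (0.0293, and adjusted p = 0.434 with an estimated correlation), receptors (0.00901, and adjusted p = 0.408 with an estimated correlation) and cadherins (0.00933, and adjusted p = 0.388 with an estimated correlation) were also placed higher by camera over the 3 ages. The cell cycle call was lost without E14.5 Htr3a-KO array 3 (0.160), E18.5 control array 1 (0.0696), E18.5 Htr3a-KO array 3 (0.0576) or P2 control array 1 (0.0616). Oligodendrocyte markers lost it without E14.5 control array 3 (0.175), E14.5 Htr3a-KO array 2 (0.0646), E18.5 control array 1 (0.109), P2 control array 3 (0.108) or P2 Htr3a-KO array 1 (0.107). Receptors lost it without E14.5 control array 3 (0.0735), E18.5 Htr3a-KO array 1 (0.0617), P2 control array 2 (0.109) or P2 Htr3a-KO array 2 (0.0693), and cadherins without E18.5 control array 2 (0.128), P2 control array 2 (0.104) or P2 Htr3a-KO array 3 (0.0520). Interneuron lists were not called over the 3 ages with the main scaling. MGE markers averaged 0.21 at E14.5, −0.12 at E18.5 and −0.28 at P2. At P2 their camera adjusted p was 0.0767, and 0.0469 with quantile normalization and 0.0428 with median centring, which call the list lower. CGE markers had 1 of 20 down, Htr3a, with the list placed higher by camera (adjusted p = 0.0612, and 0.0226 with median centring, which calls it, at a mean of −0.01), GABAergic markers an adjusted p of 0.0827 and MGE markers 0.891. Migration machinery had 0 of 40 past the threshold (0.891), synaptic genes 0 of 30 (0.155), apoptosis genes 0 of 20 (0.965), excitatory markers 0 of 17 (0.891), microglia markers 0 of 18 (0.538), erythroid markers 0 of 8 (0.255) and sex-linked genes 0 of 4 (0.0868, and 0.0371 with median centring). Serotonin genes had 1 of 8 down, Htr3a itself (0.469). The median, mean and test of a list differed in sign for 5 lists at E14.5, 6 at E18.5, 5 at P2 and 2 over the 3 ages, none of them called.

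The series title names a PlexinA4 and Semaphorin3A exchange between interneuron classes. The cells were sorted as CGE interneurons, so the values below do not test an exchange with another class. Plxna4, the receptor gene, was 9.86 ± 0.23 in control and 9.80 ± 0.60 in Htr3a-KO at E14.5 (adjusted p = 0.997), 10.35 ± 0.37 and 10.50 ± 0.34 at E18.5 (0.836), and 9.81 ± 0.04 and 9.67 ± 0.17 at P2 (0.926). Sema3a, the ligand gene, was 8.93 ± 0.18 and 9.02 ± 0.13 at E14.5 (0.996), 9.10 ± 0.30 and 8.89 ± 0.08 at E18.5 (0.752), and 8.09 ± 0.45 and 7.69 ± 0.57 at P2 (0.713). Nrp1, the co-receptor gene, was 11.06 ± 0.34 and 11.40 ± 0.18 at E14.5 (0.983), 11.38 ± 0.49 and 11.32 ± 0.19 at E18.5 (0.952), and 10.15 ± 0.44 and 9.96 ± 0.60 at P2 (0.911). Over the 3 ages the difference was −0.02 for Plxna4 (SE 0.15, adjusted p = 0.978), −0.17 for Sema3a (SE 0.14, 0.667) and 0.03 for Nrp1 (SE 0.17, 0.971). Each gene was read from 1 probe set, the one with the highest mean. In the simulated values 47.8%, 41.8% and 43.3% of 1.5-fold changes were recovered at E14.5, E18.5 and P2. These shares are over genes drawn at random. The SEs of Plxna4, Sema3a and Nrp1 over the 3 ages lay above the median of 0.0846 over all genes. Changes of 1.5-fold and more in these genes could therefore be missed. Gad1 differed by −0.28 (0.562) and Gad2 by −0.39 (0.572). The semaphorin, plexin and neuropilin list had 0 of 29 past the threshold over the 3 ages (adjusted p = 0.0917, and adjusted p = 0.388 with an estimated correlation), and other guidance genes 0 of 42 (0.232).

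The effect of losing Htr3a was compared between ages. For Htr3a itself the difference was larger at E18.5 than at E14.5, by −2.76 (SE 0.366, adjusted p = 0.0207), the 1 gene that passed in this contrast against 1032 at an unadjusted p under 0.05. For Htr3a P2 against E18.5 gave 1.56 (adjusted p = 0.644) and P2 against E14.5 −1.20 (adjusted p = 0.760). In limma 0 genes passed in these 2 contrasts, against 1033 and 900 at an unadjusted p under 0.05, and 0 passed the F test over the 3 ages, against 1033. The F test gave 1 gene without E14.5 control array 1, 13 without E14.5 control array 3, 3 without E14.5 Htr3a-KO array 3, 1 without E18.5 control array 1 and 3 without P2 control array 3. With Htr3a left out, since its deletion is shared by design and an alternative chosen after seeing the data, Lars2 was shared by the calls of all 3 ages and Pts by E18.5 and P2 (Fisher's exact test, two-sided, adjusted p = 4.41e-08 for E18.5 and P2, 2.10e-04 for E14.5 and E18.5 and 2.80e-04 for E14.5 and P2). At an unadjusted p under 0.01 these pairs shared 26, 27 and 18 genes of the same direction without Htr3a, where chance gives 4.84, 2.97 and 1.42.

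Genes changed with loss of Htr3a lay on its own chromosome more often than elsewhere. Over the 3 ages, with Htr3a left out, 7 of 291 genes within 20 Mb of Htr3a on chromosome 9 passed (2.41%), against 34 of 13912 elsewhere (0.244%; Fisher's exact test, two-sided, odds ratio 10.1, adjusted p = 6.98e-05 over 4 comparisons). At P2 it was 2 of 291 (0.687%, adjusted p = 0.00489), at E18.5 1 of 291 (0.344%, adjusted p = 0.0541) and at E14.5 0 of 291 (adjusted p = 1). Il18, Pts, Rps25, Tmem25, Cep164, Dis3l, Abhd14a, Ppm1m, Cacna2d2 and Lars2 are all on this chromosome, Pts within 10 Mb of Htr3a. The whole of chromosome 9, an alternative chosen after seeing the data, had 17 of 799 genes past the threshold (2.13%) against 24 of 13404 elsewhere (0.179%, adjusted p = 8.10e-11). Lars2 was measured by 3 probe sets, and the others gave 0.01 and −0.28 over the 3 ages.

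**Figure D3:**
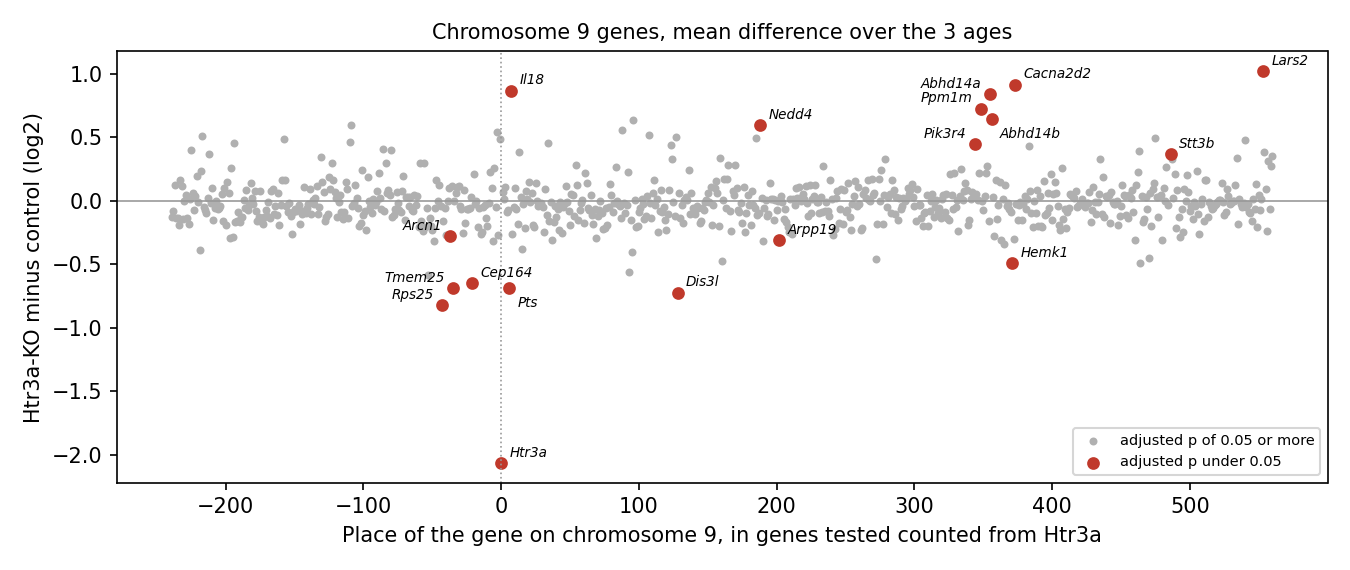
Htr3a-KO minus control log2 difference, mean over the 3 ages, of each tested gene on chromosome 9, in order along the chromosome counted in genes from Htr3a; red points passed at an adjusted p under 0.05. Lars2, at 1.02, and Htr3a, which fell 4.19-fold, lie at the ends of the range.

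Differences in Htr3a-KO samples were set against the change with age in control arrays that shared no array with them. Across 14292 genes, which are not independent replicates, the E14.5 difference followed the change from E18.5 to P2 with r = 0.372 (Spearman's coefficient 0.282). The highest absolute r of the other 9 splits of those 6 arrays was 0.322. Thus 1 of 10 splits, the real one, was as large, the smallest share that 10 splits allow. The E14.5 difference and the change from E18.5 to P2 both held higher microglia (1.31 and 1.67) and endothelial markers (0.996 and 1.06). Other lists moved in opposite directions, among them excitatory (0.20 and −0.71) and striatal markers (−1.0 and 0.23). Whether RNA of other cell types gave part of this r was not tested, so it does not show earlier maturation of the interneurons. The E18.5 difference followed the change from E14.5 to P2 with r = 0.347 (Spearman's coefficient 0.213), and 3 of 10 splits gave as large a value, the highest other 0.453. At P2 r was 0.0162 (Spearman's coefficient −0.0037) against the change from E14.5 to E18.5, smaller in absolute size than in the other 9 splits. Over the 5601 genes that differed between E14.5 and P2 controls r was 0.450, 0.488 and 0.0966. That choice of genes used control arrays that also enter the E14.5 and P2 differences. No splits were run for these 3 values, so no conclusion is drawn from them.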

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

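The tests of chromosome 9 beyond 20 Mb of Htr3a and of its genes without the called ones, of the neighbours of H2-K1 and of the shared variation of unnamed probe sets were chosen only after the result was seen, as were the covariates for microglia and endothelial genes.

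The Htr3a-KO minus control difference of Htr3a RNA itself differed between ages, by −2.76 at E18.5 against E14.5. Control Htr3a was 10.34 at E18.5 and 8.04 at E14.5, while Htr3a-KO arrays read 6.83 and 7.30. Most of the −2.76 was thus the rise of 2.29 in control arrays, and it does not show a different effect of the loss at the 2 ages. A biological difference between the ages was not tested further.

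Probe sets outside the gene comparisons also differed between genotypes. Of those without a single gene name, 2 passed at E14.5, 713 at E18.5, 3 at P2 and 24 over the 3 ages, when tested by themselves in limma. At E18.5 644 of the 713 were higher in Htr3a-KO, and 115 of all unnamed probe sets passed when adjusted over all probe sets. The mean of the 644 was 7.63 ± 0.04 in E18.5 Htr3a-KO and 6.55 ± 0.42 in E18.5 control, against 6.52 ± 0.19 and 6.57 ± 0.12 in control and Htr3a-KO at E14.5 and 6.88 ± 0.39 and 7.02 ± 0.30 at P2.

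For these 644 probe sets a factor of single arrays may contribute, since over the 12 arrays of the other ages their deviations from group means went together with a mean correlation of 0.524, where the highest of 100 random sets gave 0.0827. With the 3' to 5' differences of Gapdh and actin as covariates 29 probe sets passed instead of 713, which met the bound written beforehand for RNA degradation, but the median difference moved only from 1.04 to 0.88 and the median SE from 0.255 to 0.271, so this stays open, a reading made after the values were seen. Scaling of the arrays is argued against as the whole source, a reading made after the values were seen. Under the 2 other scalings 657 and 599 probe sets passed, and the median difference was 0.95 (SE 0.246) and 0.99 (SE 0.25), though the bound written beforehand asked for at least 713, and the genotype remains an open biological explanation.

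Changed genes over the 3 ages lay on chromosome 9 more often than elsewhere. Strain sequence limited to 20 Mb on either side of Htr3a is argued against as the whole source, since 10 of 508 genes beyond that window passed (1.97%), against 24 of 13404 on other chromosomes (Fisher's exact test, two-sided, p = 2.30e-07). A DNA difference along a longer part of chromosome 9 stays open, since its genes' differences went together between ages with a mean r of 0.275, against 0.207 at most on the 19 other chromosomes, but called genes agree between ages by their selection, and without them it was 0.155 against 0.166 at most. Sequence variants under the probes stay open, as does an effect of Htr3a loss, which was not tested apart from them. In 5 of 9 called genes with another probe set (55.6%) one moved the same way at an unadjusted p under 0.05 in limma. This met the bound written beforehand, but the exact binomial interval of 21.2% to 86.3% spans it, a reading made after the value was seen. In 3 of the 9 (Arpp19, which also has one moving the same way, Cep164 and Lars2) another probe set moved the opposite way at that p, against 1 of 12 on other chromosomes.

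For H2-K1 and H2-D1, higher in Htr3a-KO at all 3 ages, a larger share of microglia or endothelial cells is argued against as the whole source of H2-K1, which was 1.42 (SE 0.18) and stayed at 1.25 (SE 0.132, adjusted p = 9.87e-04) with their list means as covariates, where its range over alternatives was 1.66e-04 to 0.0379. H2-D1 went from 1.19 to 1.08 with an SE of 0.211 and an adjusted p of 0.10 (0.00268 to 0.10 over its alternatives), so its call ended, with a smaller difference, nearly the same SE and 10 genes past the threshold in place of 42. Which of these ended it was not tested. A DNA difference at the MHC on chromosome 17 may contribute, since 12 of 190 genes within 5 Mb of H2-K1 had an unadjusted p under 0.01 (6.32%) against 2.97% elsewhere (Fisher's exact test, two-sided, p = 0.0155). A response to Htr3a loss stays open and was not tested.

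Other splits of the arrays were counted for each result. For the 42 genes over the 3 ages 1 of 100 splits, the real one, gave as many, and the highest other gave 1. The other splits were drawn at random, and 1 of 100 is the smallest share possible, so chance is unlikely but not excluded there. For the 11 lists over the 3 ages 25 of 100 splits gave as many, the highest other 17, so chance cannot be excluded. For the 0 genes of the F test 100 of 100 did, the highest other 11, but any split reaches 0, so this says nothing about chance. The 10 splits of 6 arrays are too few for a share under 0.05. Their real and highest other counts of genes were 2 and 19 at E14.5 (3 splits as large), 3 and 0 at E18.5 (1), 5 and 101 at P2 (2), 1571 and 4 for E18.5 against E14.5 (1) and 2818 and 1 for P2 against E18.5 (1). For lists they were 9 and 11 (3 splits), 11 and 13 (3), 6 and 16 (8), 11 and 14 (3), and 9 and 14 (4). The split with 101 genes set P2 control arrays 1 and 2 and Htr3a-KO array 1 against the other 3. Their means of the 644 unnamed probe sets above were 6.73, 6.59 and 6.68, against 7.32, 7.18 and 7.21 in the others. The split with 19 set E14.5 control arrays 1 and 2 and Htr3a-KO array 3 against the others. These means did not part its sides, at 6.74, 6.42 and 6.70 against 6.39, 6.47 and 6.55. Both splits point to a structure of the samples whose source was not tested.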

How the results depend on the processing

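The covariates, the run without the 2 arrays with the highest microglia list mean, the whole chromosome and the overlap without Htr3a were tests chosen only after the result was seen. Of 443 alternatives to 27 results 352 were counted as the same, 60 as weaker, 31 as stronger and 0 as reversed. A count was the same within 1.5-fold of its main value. A correlation was the same if it moved by less than its SD over splits. Other results were the same if they stayed on their side of the threshold. Only the Htr3a level could be counted as reversed. Of 555 alternatives for the 23 named genotype calls 422 still passed and 133 did not. Of 1507 for 89 named age calls 1449 still passed and 58 did not. Where a value changed, the cause was not tested. E14.5 (2 genes) gave 1 with the mean of a gene's probe sets, 119 with array weights, 0 with the replicate block, 5 with all probe sets, and 0 with only the 6 arrays, with the covariates and without the 2 arrays. E18.5 (3 genes) gave 5 with no filter, 14 with the mean of probe sets, 18 with median centring, 876 with array weights, 16 at a false discovery rate of 0.10, 19 with all probe sets, 6 with the covariates and 5 without the 2 arrays. P2 (5 genes) gave 3 with quantile normalization, 3 with trended and robust variance, 8 with array weights, 0 with the replicate block, 9 with all probe sets, 0 with only the 6 arrays, 1 with the covariates and 2 without the 2 arrays. Htr3a at P2 was −1.94 with the replicate block (adjusted p = 0.0623) and with only the 6 arrays (0.0542), and −2.03 without the 2 arrays (0.0574), against 0.00658 to 0.121 over all alternatives. Over the 3 ages (42 genes) array weights gave 318, the replicate block 14, a rate of 0.10 67, at least 1.5-fold 20, the covariates 10 and no 2 arrays 12. E18.5 against E14.5 (1571) gave 3166 with array weights and 2391 at 0.10, and P2 against E18.5 (2818) 1694 at 1.5-fold or more and 1665 with only the 6 arrays. The F test (0) gave 8 with array weights and 1 at 0.10. Lists called with an estimated correlation were 0 in all 6 comparisons. With fry they were 0 at E14.5, 1 at E18.5, 0 at P2, 1 over the 3 ages, 7 for E18.5 against E14.5 and 8 for P2 against E18.5. Those of the genotype comparisons at E18.5 and over the 3 ages were the serotonin list, which holds the deleted Htr3a. Under quantile normalization and median centring 0 of 57 list calls changed direction and 1 was lost, and of 87 lists not called 8 were gained. E18.5 lists were 5 with the covariates and P2 lists 3 without the 2 arrays. Near Htr3a the share was 5.50% at E14.5 for an unadjusted p under 0.01 (adjusted p = 4.60e-06), 0.585% at E18.5 in 10 Mb (0.0479), 0.25% on the whole chromosome (0.00421) and 0.585% at P2 in 10 Mb (0.0631). Leaving out 1 array gave 0 to 135 genes at E14.5, 2 to 20 at E18.5, 0 to 21 at P2, 17 to 128 over the 3 ages, 916 to 1417 and 1823 to 2901 for the age comparisons, 0 to 13 for the F test, 7 to 13 lists at E18.5, 3 to 8 at P2, and −2.03 to −1.78 for Htr3a at P2. The labels do not say whether equal numbers pair the arrays. Over 9 pairs of equal number the correlations of their deviations were −0.54 to 0.30, 2 over 0.1. Deviations were taken within groups of 3 arrays, so this check cannot exclude pairing. Signal over background limits dim genes, and no alternative failed to run.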

Other observations

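The tests of single genes shown here were chosen only after the result was seen, while the age comparisons, the microglia list and its comparisons were fixed before.

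A few more genes moved with age in control arrays. Between E18.5 and P2 the neuropilin gene Nrp1 fell from 11.38 to 10.15 (adjusted p = 0.00957, limma) and the ligand gene Sema3a from 9.10 to 8.09 (adjusted p = 0.0105). Both calls were lost without P2 control array 2, where Nrp1 gave −0.97 (0.0515) and Sema3a −0.79 (0.0567). The neuropeptide gene Vip, of a CGE interneuron class, rose from 5.64 to 7.43 (adjusted p = 0.00236). Between E14.5 and E18.5 Npas1 rose from 6.36 to 8.05 (adjusted p = 0.00396). The extracellular matrix gene Reln rose from 11.39 to 12.50 (adjusted p = 0.0190), a call lost without E14.5 control array 1 (0.0941) or 2 (0.0673) or E18.5 control array 1 (0.0927). Adarb2 rose from 7.09 to 8.69 (adjusted p = 0.0203), a call lost without E14.5 control array 3 (0.0864) or E18.5 control array 2 (0.0705) or 3 (0.0756).

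Microglia list means differed between genotypes in opposite directions at E14.5 and P2. The list mean was 1.31 higher in Htr3a-KO at E14.5 (0.77 without Htr3a-KO array 1; adjusted p = 1.19e-10, and adjusted p = 0.281 with an estimated correlation), with 0 of 18 members past the threshold. It was 0.11 higher at E18.5, and at P2 it was 1.37 lower (0.65 without control array 1; adjusted p = 4.18e-09, and adjusted p = 0.657 with an estimated correlation), again with 0 of 18 past the threshold and a control SD of 1.38. The difference between ages was not tested for the list, and the values are given without an explanation.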
